A study of Stylophora pistillata with 6 samples.

How the data were processed

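RNA was sequenced from subapical branch tissue of *Stylophora pistillata*, a branching reef coral that houses photosynthetic algae in its tissue. The 6 samples were 3 control nubbins (small coral fragments) and 3 nubbins kept in darkness. Per the labels' protocols, both groups were kept at 25 °C and fed the same diet, total RNA was extracted from crushed frozen fragments with a column kit and a DNase step, and Illumina libraries were made. The group and the replicate number of each sample were taken from its title, and each column of the deposited table was assigned to the sample whose description carries the same name; 0 columns were left unused.

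The authors deposited estimated counts: the number of reads assigned to each transcript in each sample, not scaled to depth, for 36031 RefSeq predicted transcripts. Of these, 33152 carry the XM prefix of predicted mRNAs and 2879 the XR prefix of predicted non-coding RNAs. Between 23.6% and 33.6% of the values in a library were not whole numbers. Per the submitters' processing notes, the tools were fastp, Salmon 0.11.4 and DESeq2. The notes give neither the role nor the order of these tools. In general use, fastp trims reads, Salmon estimates transcript abundance and divides reads between transcripts that share sequence, and DESeq2 tests for differential expression. The genome build, annotation release, settings and strandedness are not given in the sources used here. Where shared reads are divided, the estimates of isoforms and of near-identical gene copies depend on each other, and a read of one transcript can appear under a similar one. Library totals are sums of the deposited estimates, and how reads of the algae were treated is not given in the sources used here.

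Transcript accessions were paired with gene symbols through a RefSeq gene table of the assembly jaStyPist1.2. Ignoring the version number, 18711 transcripts (51.9%) matched one of 14682 symbols; with the version, 100 matched. All matched symbols but 1 are LOC numbers, which identify a locus without naming its product. The table holds no product names, so the 30 lists of gene functions and cell type markers and the product name families fixed before the data were examined were not analysed here: 0 of the lists' symbols were found. The assembly of the table may differ from the one behind the counts, so no coordinates are given.

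Estimates were rounded to whole numbers. Transcripts were filtered with filterByExpr, which kept 26906 (24992 XM and 1914 XR) holding at least 99.68% of the reads of every library. Libraries were scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, group as the only term, all 6 libraries) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested transcripts and a threshold of 0.05. CPM values were computed by edgeR from the TMM-scaled libraries. The standard error of a log2 fold change was taken as its size divided by the square root of F. Where every library of a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group's 3 libraries together; it covers counting error only. For 1 ratio resting on 1 to 3 reads, an exact Poisson 95% interval is given, also for counting error only.

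The rule for named transcripts was fixed before the data were examined. Without product names it takes the 2 transcripts with the largest rise and the 2 with the largest fall among those past the threshold, with a mean log2 CPM of at least 2 and with the 3 libraries of one group all above those of the other. All other transcripts named in the text were chosen after their values were seen: the 5 most abundant matched transcripts that rose and the 5 that fell, the 4 matched transcripts in each direction with the smallest p at a fold change of at least 8, and the single transcripts and genes named beside them. The definition of transcripts absent from one group, with its minimum of 20 reads, was also chosen after seeing the data.

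The test was checked on simulated data. Counts for the 26906 transcripts were drawn from the real means, library sizes and dispersions, with 200 transcripts of at least 4 CPM changed. For darkness against control, 16 of 100 changes of 2-fold and 56 of 100 of 4-fold were recovered, all in the right direction, and 9 unchanged transcripts were called; so few changed transcripts make the adjustment stricter than in the real data. A test of unequal change among the transcripts of a gene (edgeR diffSpliceDGE) recovered 29 of 50 genes with 4-fold changes in opposite directions and called 6 unchanged genes among 1832. The test of adjacent genes was also run on a random and on a correlated series.

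Library totals ran from 17819857 to 33307374 estimated reads, so 3 reads stand for 0.0901 to 0.168 CPM depending on the library. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom was at least 26.3 in every pair. The labels do not say whether the nubbins of a group came from separate colonies, so p-values measure the spread between these samples, which may be smaller than that between colonies. Both groups use the replicate numbers 1, 2 and 3, which were not taken as pairs. Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters and thresholds, the replicate number as a block, and leaving out each library. Thinning every library to the smallest total, summing transcripts to genes, using only transcripts with whole estimates in all 6 libraries (19924 of 36031) and leaving out 2 transcripts that vary together were chosen after seeing the data. Bias by GC content or transcript length was not analysed here, as neither property was at hand.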

Results

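The transcriptome of *S. pistillata* branches was measured in 3 nubbins under a cycle of 12 h light and 12 h dark at 230 μmol photons per m² per s, and in 3 nubbins kept for 6 months in complete darkness. The dark-kept nubbins looked bleached, the pale state of a coral that has lost algae or their pigment. The 3 control libraries held 19585374, 17819857 and 20218232 estimated reads and the 3 darkness libraries 31826758, 33307374 and 29123213. Darkness libraries held 1.64 times more estimated reads on average (31419115 ± 2121657 against 19207821 ± 1242964 reads, SD, n = 3 each). Depth here means this total of estimates for the listed transcripts, not the number of reads sequenced. What made the totals differ was not tested. Every darkness library exceeded every control (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give), so depth and light cannot be told apart by the design. Between 26591 and 28956 transcripts had reads in a control library and between 29347 and 29491 in a darkness library.

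The darkness libraries resembled each other more closely than the controls did. Pearson correlations of log2 CPM across transcripts ran from 0.88 to 0.887 among darkness libraries, from 0.805 to 0.833 among controls and from 0.737 to 0.789 between the groups. The first principal component held 41.6% of the variance and separated the groups, and the second, with 21.5%, set control replicate 2 apart from control replicates 1 and 3.

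**Figure D1:**
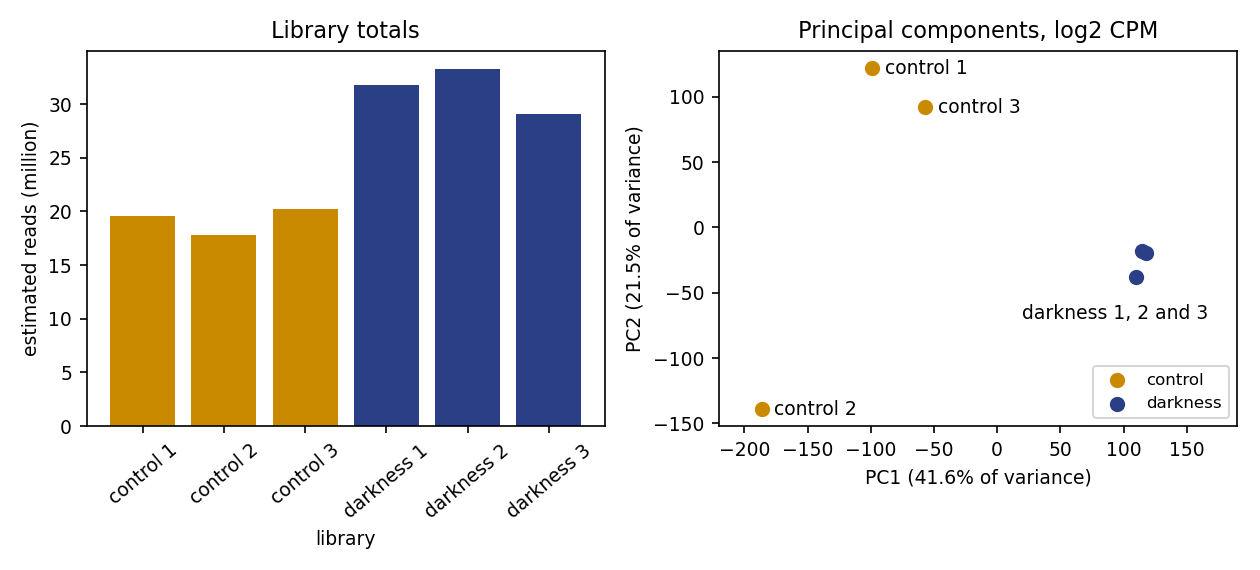
Left, estimated reads per library on a linear axis that starts at 0, 1 bar per library. Right, the first and second principal components of log2 CPM over the 26906 tested transcripts, 1 point per library: the 3 darkness libraries (blue) lie close together at the right, and the 3 controls (ochre) are spread out at the left, with control 2 lowest.

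The comparison of darkness with the light cycle asks which transcripts of the coral differ after 6 months without light. In darkness 2173 transcripts were higher and 2812 lower, together 4985 of the 26906 tested (18.5%; edgeR quasi-likelihood test, adjusted p under 0.05). The median change was 0.99 on the log2 scale among the higher and −1.04 among the lower transcripts, and 2552 changed at least 2-fold (1079 higher and 1473 lower). In all 4985 the 3 libraries of one group lay above the 3 of the other, which passing the test itself favours. Such separation held for 43.7% of the tested transcripts, where chance gives 10% for a single transcript. Transcripts share the same 6 libraries, so the 43.7% was not tested against the 10%. At least 8-fold changes by the fitted values numbered 685, with 233 higher and 452 lower. Of these, 381 had reads in both groups, 73 higher and 308 lower. The transcripts that rose took 8.5% to 9.47% of the reads in controls and 17.6% to 18.1% in darkness, and those that fell took 22.8% to 25.4% and 12.1% to 12.3%; the transcripts were chosen by the test, so these shares are no independent evidence. Left out one at a time, each of the darkness replicates 1, 2 and 3 and control replicate 1 lowered the count by over 1.5 times, to 2638, 2203, 2121 and 3089, while 1785 transcripts (612 higher and 1173 lower) were called in every such fit. DESeq2 called 9467, and with scaling by library totals the lower transcripts were no longer the majority (2524 higher and 2363 lower).

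**Figure D2:**
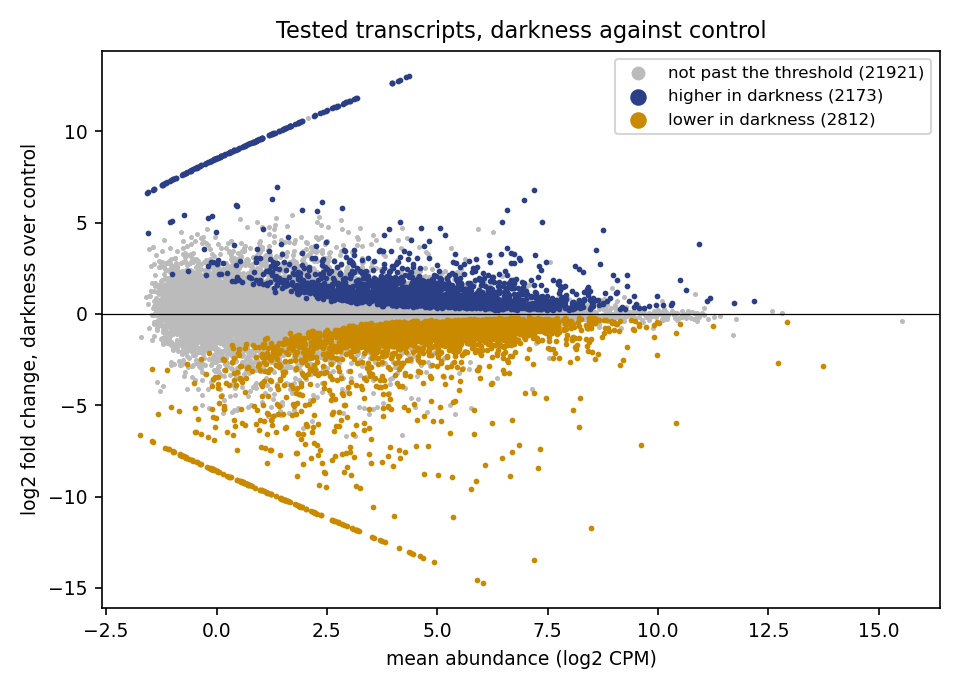
Log2 fold change of darkness over control against mean abundance (log2 CPM), 1 point per tested transcript; blue marks the 2173 higher and ochre the 2812 lower transcripts past the threshold. The straight lines of points at the top and bottom are transcripts with 0 reads in every library of one group, whose fitted fold depends on a small added count.

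The 4 transcripts named by the rule had estimated reads in one group only. Of the 4, only XM_022922209.1 had whole estimates in all 6 libraries. For the other 3 at least, a 0 may also come from division of reads with similar transcripts, which the bounds below do not cover. XM_022939385.1 had 0 reads in each control and 2030, 958 and 951 in the darkness libraries, at least 755.3-fold higher (adjusted p = 0.00605, edgeR). XM_022943470.1 had 0 reads in each control and 1291, 1452 and 1043 in darkness, at least 726-fold higher (adjusted p = 0.000952, edgeR). XM_022923822.1 of LOC111321050 had 1652, 1967 and 3816 reads in the controls and 0 in each darkness library, at least 4308-fold lower (adjusted p = 0.00395, edgeR). XM_022922209.1 had 1133, 4455 and 471 reads in the controls and 0 in darkness, at least 3511-fold lower (adjusted p = 0.0353, edgeR). XM_022939385.1, XM_022943470.1 and XM_022922209.1 matched no gene symbol. Most reads of XM_022922209.1 were in control replicate 2, without which its fitted log2 fold change, which depends on a small added count and is no bound, went from −14.56 to −13.14. Its call was lost without control replicate 1 and without any of the 3 darkness replicates (adjusted p from 0.0774 to 0.0901), and limma-voom called only XM_022943470.1 among the 4 (adjusted p = 0.168, 0.113 and 0.545 for XM_022939385.1, XM_022923822.1 and XM_022922209.1).

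Under a definition chosen after the values were seen, 232 transcripts had 0 reads in every library of one group and at least 20 in every library of the other. Of these, 130 were absent from the controls and 102 from the darkness libraries, and all passed the threshold in edgeR. The number moved with the minimum, to 310 at 10 reads and 132 at 50 reads, and 198 met the definition with every library thinned to one depth. After thinning the larger side turned over, with 90 absent from the controls and 108 from the darkness libraries. With 1 library left out the definition asks less, and 354 to 481 transcripts met it. XM_022926985.1 of LOC111323593 came close to this pattern, with 5444, 3756 and 7445 reads in the controls and 0, 0 and 2 in darkness. Its ratio was 14470, with a 95% interval of 4005 to 119500 for counting error alone. Both darkness reads were in replicate 3, and without it the fitted log2 fold change went from −13.49 to −15.81.

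Of the matched transcripts, looked up after the values were seen, the 4 with the smallest p among rises of at least 8-fold belonged to LOC111343638, LOC111325565, LOC111336571 and LOC111333660. LOC111343638 went from 3.21 ± 0.659 CPM in controls to 246 ± 30.4 in darkness (SD, n = 3), 76.6-fold higher. LOC111336571 went from 33.6 ± 5.3 to 824 ± 215 CPM, 24.5-fold higher. LOC111333660 and LOC111325565 were 10.8-fold and 9.78-fold higher, from 2.3 ± 0.448 to 24.9 ± 1.59 CPM and from 19.9 ± 1.43 to 195 ± 35.1 CPM. The 4 corresponding falls belonged to LOC111335117, LOC111333578, LOC111346891 and LOC111321006. LOC111335117 went from 308 ± 42.4 CPM in controls to 0.89 ± 0.253 in darkness, 345-fold lower. LOC111346891 went from 587 ± 114 to 7.87 ± 0.73 CPM, 74.5-fold lower. LOC111333578 and LOC111321006 were 92.5-fold and 27.3-fold lower, from 77.1 ± 5.37 to 0.83 ± 0.142 CPM and from 81.4 ± 8.01 to 2.98 ± 0.32 CPM. Adjusted p in edgeR was between 0.000402 and 0.000954 for these 8, and all 8 kept their call with any library left out (adjusted p at most 0.0113).

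The most abundant matched transcripts were also chosen after the values were seen. Each symbol here and in the paragraph above stands for 1 transcript, not for the sum of its gene. Among those that rose, LOC111324981, a non-coding RNA model, went from 3550 ± 435 to 5750 ± 150 CPM (1.62-fold, adjusted p = 0.0101, edgeR; SD, n = 3 throughout). LOC111322521 went from 917 ± 29.7 to 2270 ± 39.8 CPM (2.48-fold, adjusted p = 0.00072, edgeR) and LOC111325804 from 622 ± 45.4 to 2260 ± 186 CPM (3.64-fold, adjusted p = 0.000783, edgeR). LOC111344246 went from 255 ± 279 to 3630 ± 1490 CPM (14.2-fold, adjusted p = 0.0405, edgeR) and LOC111320871 from 918 ± 66.5 to 1300 ± 160 CPM (1.41-fold, adjusted p = 0.0324, edgeR). Among those that fell, LOC111329748 went from 8970 ± 243 to 6540 ± 188 CPM (1.37-fold lower), LOC111330927 from 2980 ± 434 to 1860 ± 57.7 (1.6-fold lower) and LOC111327082 from 1830 ± 241 to 893 ± 150 (2.05-fold lower). LOC111335278 and LOC111321007 were 1.47-fold and 1.4-fold lower, and adjusted p in edgeR was between 0.00956 and 0.0334 for these 5. LOC111322521 and LOC111325804 kept their calls with any library left out. LOC111324981 and LOC111329748 lost theirs without darkness replicate 3 (adjusted p = 0.0524 and 0.059, edgeR) and LOC111327082 without darkness replicate 2 (adjusted p = 0.0521, edgeR). LOC111330927 lost its call when any 1 darkness library was left out (adjusted p from 0.0501 to 0.067, edgeR). LOC111335278 and LOC111321007 lost theirs without any 1 darkness library and without control replicate 1 (adjusted p from 0.0603 to 0.12 and from 0.0735 to 0.109, edgeR). LOC111344246 kept its call only in the fit without control replicate 2, where its log2 fold change was 5.26 against 3.83 with all libraries, and LOC111320871 only in the fit without darkness replicate 1 (adjusted p in the other fits from 0.0808 to 0.111 and from 0.0613 to 0.114, edgeR).

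**Figure D3:**
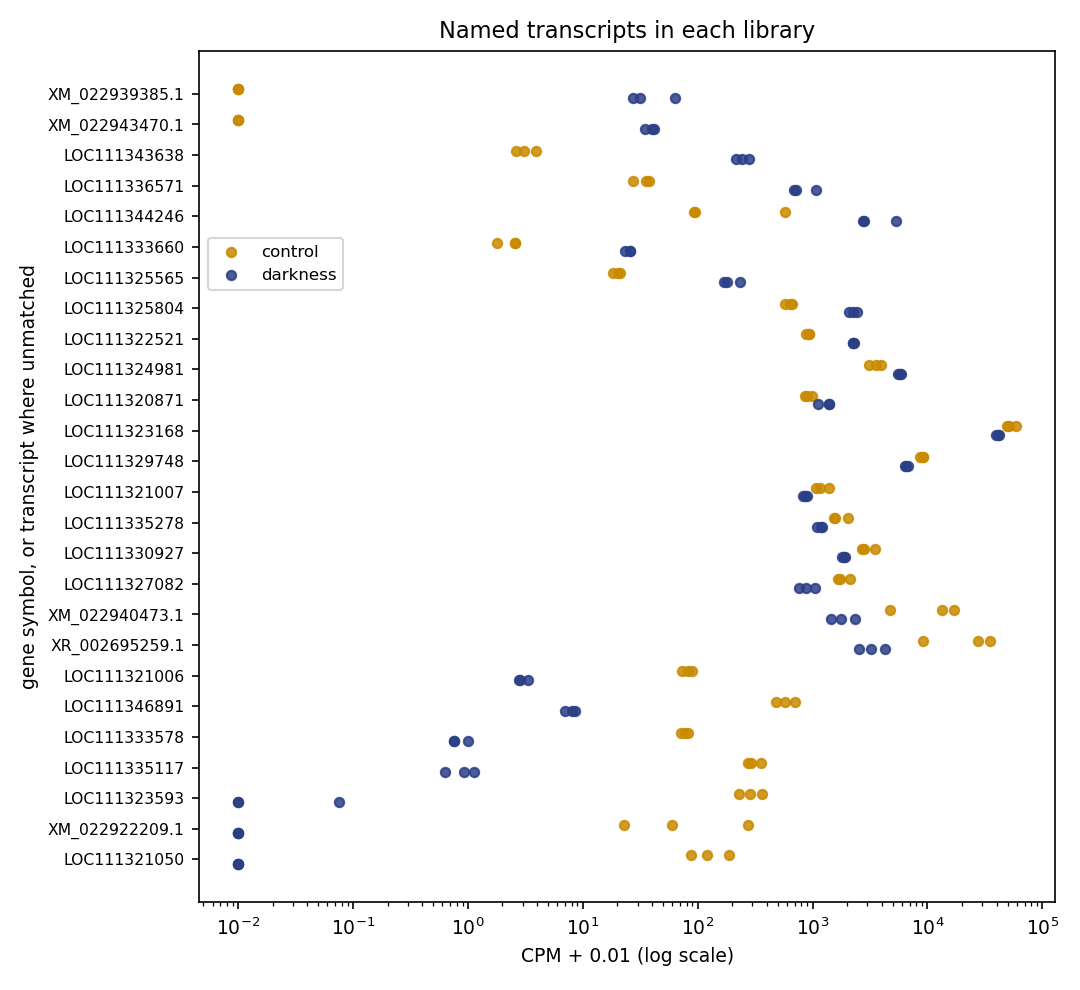
CPM + 0.01 on a log scale in each library for the named transcripts except that of Cglr2, ordered by log2 fold change, with the gene symbol or, where none matched, the transcript accession; ochre points are the 3 controls and blue points the 3 darkness libraries. Points at 0.01 are libraries with 0 reads, as in the controls for XM_022939385.1 and in darkness for LOC111321050.

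The most abundant transcript, XM_022926465.1 of LOC111323168, took 4.96%, 5.44% and 4.94% of the reads in controls and 4.22%, 4.27% and 4.13% in darkness. It did not pass the threshold (log2 fold change −0.38, SE 0.10, adjusted p = 0.0597, edgeR), and passed it in 6 alternatives. These were DESeq2 (adjusted p = 0.000518), limma-voom (adjusted p = 0.019) and, in edgeR, scaling by library totals (adjusted p = 0.0312), a stricter filter (adjusted p = 0.0474), whole estimates only (adjusted p = 0.0196) and leaving out XR_002695259.1 and XM_022940473.1 (adjusted p = 0.048). In the other alternatives run, adjusted p in edgeR was between 0.0554 and 0.208. The transcript with the next highest mean, the non-coding model XR_002695259.1, took 2.70%, 3.22% and 0.917% in controls and 0.428%, 0.337% and 0.261% in darkness, 7.2-fold lower (adjusted p = 0.0219, edgeR). XM_022940473.1 was 6.34-fold lower (adjusted p = 0.0222, edgeR). Both calls were kept only in the fit without control replicate 3, and were lost when any of the other 5 libraries was left out (adjusted p from 0.0502 to 0.0911 and from 0.0504 to 0.0925, edgeR). These 3 transcripts were chosen after their values were seen. Of them, XR_002695259.1 and XM_022940473.1 matched no gene symbol.

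Non-coding models changed less often than mRNA models. Of 1914 tested XR transcripts, 88 were higher and 129 lower (11.3%), and of 24992 XM transcripts, 2085 were higher and 2683 lower (19.1%). XR transcripts were also less abundant, with a median log2 CPM of 1.83 against 3.32. At the rate of XM transcripts of like abundance, 264 XR transcripts would have been called, against 217 observed. Of 10000 random draws matched on abundance, 8 gave as few. Transcripts are not independent replicates. The share called rose with abundance, from 6.9% to 17% and 31.7% when the tested transcripts were ranked by abundance and divided into 3 equal parts.

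With the reads of matched transcripts summed to genes, 3926 of 13183 tested matched genes changed (29.8%), 1548 higher and 2378 lower. Among 1832 genes with at least 2 tested transcripts, 443 had at least 1 called transcript and 57 had 2 or more. In 49 of the 57 the called transcripts went one way, and in 8 they went both ways. Cglr2, singled out as the only matched symbol that is not a LOC number, is the symbol of a cGAS-like receptor, a family of innate immune sensors. It had 8.26 ± 1.05 CPM in controls and 5.74 ± 1.02 in darkness (SD, n = 3) and did not pass the threshold (log2 fold change −0.52, SE 0.22, adjusted p = 0.161, edgeR).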

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

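Thinning to one depth, summing to genes, using whole estimates only and leaving out XR_002695259.1 and XM_022940473.1 were chosen after the result was seen, as were the refits of depth and similarity without 1 library. The count of changed transcripts (4985) stayed between 4418 and 5147 with RLE, upper quartile or library-total scaling, limma-voom, no filter or a stricter filter. The share of calls that were lower, 56.4%, was 58.6%, 51.3% and 48.4% under the 3 scalings in that order, so which direction held more calls depends on the scaling. DESeq2 called 9467, including 4984 of the 4985, and the cause was not tested. Requiring 2-fold left 2552, and an adjusted p under 0.01 left 1790. Leaving out 1 library gave 2121 to 4466, with 1 fewer sample in each such fit. With the replicate number as a block, 1386 were called (485 higher and 901 lower), 1374 of them shared with the 4985, in a fit with fewer residual degrees of freedom. The numbers were not taken as pairs because no label says that they pair the nubbins. The sample descriptions carry numbers of their own, whose meaning is not given. These are the same in both groups for replicates 1 and 2 but differ for replicate 3. In a check, deviations of same-numbered libraries from their group means correlated at −0.042, −0.028 and 0.031, and only control 3 correlated best with its own number. Thinning gave 4840 (4653 shared with the 4985) and leaving out the 2 transcripts 5012 (4911 shared). Whole estimates only gave 4773 of 13909 tested, of which 3176 were shared, so the set of calls depends on which transcripts are tested. Summing to genes gave 6104 of 24610 features. The excess of mean correlation within groups over that between groups, 0.0833, was 0.517 among the 500 most variable transcripts, which are chosen for their spread, and 0.0649 to 0.109 with 1 library left out. The depth ratio of 1.64 stayed between 1.58 and 1.7. Among the 27 named transcripts no alternative turned a direction: 391 refits kept the side of the threshold, 52 lost the call and 6 gained it. In simulated data 16 of 100 changes of 2-fold were recovered, but with 200 transcripts changed the adjustment is stricter than with the 4985 real calls, 1017 of them under 1.5-fold, so this rate does not carry over to the real comparison. The gene list and product name family tests fixed before the data were examined were not run, for want of product names.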

Other observations

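Tests chosen or altered after the result was seen were that of other splits for the absent transcripts, that of ambiguous division of reads for the spread, and that of the 2 transcripts that vary together; the absent transcripts and the larger spread of the controls had themselves been seen before any test of them was written. Adjacent genes tended to change alike. Using the gene order of the assembly jaStyPist1.2 and reads summed to genes, the log2 fold changes of 7680 adjacent pairs correlated across genes at a Spearman r of 0.107, above all 10000 shuffles of gene order (highest 0.047; p = 1e-04, the smallest they can give). Where both neighbours were called, 537 of 825 pairs (65.1%) went the same way, against 53.2% expected from the shares of the directions. There were 62 runs of at least 3 adjacent genes called in one direction, 50 lower and 12 higher, where 1000 shuffles gave a median of 33 and at most 54. In one run of 5, LOC111325803, LOC148724429, LOC111325805, LOC111325808 and LOC111325804 rose by 1.43, 0.51, 1.78, 1.24 and 1.86 on the log2 scale. In one run of 6, LOC111335706, LOC111335683, LOC111335697, LOC111335699, LOC111335680 and LOC111335700 changed by −0.36, −0.62, −1.12, −1.44, −1.61 and −1.03. As a hypothesis, adjacent genes may share regulation or be duplicates that respond alike, which were not tested apart. Reads divided in fractions between similar neighbours are argued against. Among 3608 pairs of genes with whole estimates in all 6 libraries r was 0.117, again above all shuffles (highest 0.0592). A whole estimate does not show that no read was shared, so shared reads assigned to a single copy are not covered. Genes are not independent replicates.

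Transcripts of a gene changed unequally in 56 of 1832 genes (edgeR diffSpliceDGE, adjusted p under 0.05), against at most 17 in the other 9 splits of the libraries. These 10 splits are too few for a share under 0.05, and the other 9 mix the groups, which lowers their counts if the groups differ. In LOC111323780, XM_022927207.1 had 0 CPM in controls and 12.8 ± 1.69 in darkness, and XM_022927208.1 had 9.36 ± 2.29 and 0 (SD, n = 3), while the gene's sum did not pass the threshold (log2 fold change 0.45, SE 0.22, adjusted p = 0.193, edgeR). In LOC111339139, XM_022945727.1 went from 0 to 16.1 ± 7.14 CPM as XM_022945728.1 went from 280 ± 31.2 to 138 ± 19, and the gene's sum fell (log2 fold change −0.86, SE 0.13, adjusted p = 0.00483, edgeR). In LOC111326129, which had the smallest p of this test, XM_022930064.1 went from 51.2 ± 25.7 to 0 CPM and the gene's sum fell as well (log2 fold change −0.80, SE 0.08, adjusted p = 0.00123, edgeR). Its XM_022930065.1 went from 14.7 ± 10.6 to 28 ± 5.27 CPM and XM_022930066.1 from 138 ± 33.8 to 89.9 ± 8.98, neither past the threshold (adjusted p = 0.396 and 0.0901, edgeR). A different use of transcripts in darkness is a hypothesis that these counts leave open, since division of shared reads could give an exchange such as that in LOC111323780. The lower sums of the other 2 genes do not decide this, since a fall of the whole gene can go with such an exchange. The test also made 6 false calls beside 29 true ones in simulated data.

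The real grouping gave 4985 changed transcripts in edgeR and the highest of the other 9 splits gave 0, so 1 of the 10 splits reached the real count; 10 splits are too few for a share under 0.05. In the other splits 230 to 452 transcripts had an unadjusted p under 0.05, against 8780, and DESeq2 called 78 to 130, against 9467. Each of these splits puts libraries of both groups on each side, so any difference between the groups adds to the spread within a side. Their low counts follow in part from that, and are not those of a comparison without a difference.

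The real grouping left 232 transcripts absent from one group and the highest other split 68, so 1 of the 10 splits reached the real count, again too few for a share under 0.05. The other splits mix the groups here too, which lowers their counts if the groups differ. After thinning to one depth, 82.3% of the 232 still met the definition, with over 90% set to exclude lower depth of the controls. That test cannot decide, since thinning adds no reads and a transcript left the 232 only when its reads fell under the minimum. A later test on expected reads was dropped because the minimum of 20 reads fixes its outcome. The definition itself leaves little room for depth. Darkness libraries were 1.64 times deeper on average. All 130 transcripts absent from controls had at least 20 reads in each of them, and 69 had at least 50. The minimum of 20 reads is part of the definition, so these values are no independent test of depth for the 130. Lower depth of the controls would not leave transcripts absent from the deeper darkness libraries, where 102 were absent. Exchange of reads between transcripts of one gene cannot be told apart for the 76 that share a gene with other listed transcripts. Of these, 47 (61.8%, exact binomial 95% interval 50% to 72.8%) belong to a gene whose sum changed by less than 2-fold and 29 do not. Another 57 are the only listed transcript matched to their gene, and the others matched no gene. Only 71 of the 232 had whole estimates in all 6 libraries, against 19924 of all 36031 listed. For the rest at least, division of reads with similar transcripts of other genes cannot be told apart either. A response to darkness and a difference in alleles between colonies may each contribute and were not tested, as the labels do not give the colony.

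Controls varied more than darkness libraries, with a biological coefficient of variation of 60.2% to 72.2% per pair against 48.6% to 51.4%. Lower depth acting through counting error is argued against. After thinning to one depth the highest darkness pair was 45.7% and the lowest control pair 59%. Thinning acted on the finished estimates and left the division of shared reads as it was. Depth acting through that division therefore cannot be told apart. Control replicate 2 alone is argued against over all tested transcripts, since controls 1 and 3 differed by 60.2%. For ambiguous division of reads, the test as first written asked whether control and darkness pairs overlap among transcripts with whole estimates, and they did, by 0.1 (lowest control pair 20.1%, highest darkness pair 20.2%), which would have counted for it. A margin of 1 SD of the darkness pairs was required only after that value was seen, so this explanation cannot be told apart; the ratio of the group means was 1.46 in that set and 1.35 over all tested transcripts. Because the 20.1% is that of controls 1 and 3, control replicate 2 may still carry the difference in that set, and a larger spread among light-kept nubbins stays open as untested.

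XR_002695259.1 and XM_022940473.1 rose and fell together over the 6 libraries, including control replicate 3, where both were far lower than in the other controls. Together they took 1.39% to 4.78% of the reads in controls and 0.411% to 0.662% in darkness. Their ratio was 2.08, 2.07 and 1.94 in the controls and 1.83, 1.83 and 1.75 in darkness, higher in every control than in every darkness library. The SD of its log2 over the 6 libraries was 0.102, but the pair was picked because its members vary together, so this value cannot count for one RNA source. One RNA source for both may be involved and cannot be told apart from separate sources that change alike; a fixed ratio would not by itself give the difference between the groups, which was not tested.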
